A study of Arabidopsis thaliana with 4 samples.

How the data were processed

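Total RNA of dissected shoot apices was hybridised to 1 array per sample, with 2 samples of Col-0 plants from 30 short days and 2 from 30 short days followed by 7 long days. The samples were grouped by the growth conditions in their labels. The table deposited by the authors holds 1 linear intensity per probe set and array, for 22746 probe sets and 64 control probe sets. The mean of each array without its lowest and highest 2 percent was 500.033 to 500.036, so the authors had scaled the arrays to a common level. The software that made the signals and the scaling is not given in the sources used here. The number of arrays limits the precision of every value.

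Probe sets were named from a table that pairs the array's probe sets with genes, with symbols updated through gene identifiers to the TAIR10.1 gene table. It paired 13513 probe sets with 1 gene and 503 with several, and 8730 probe sets are unnamed here. Genes were named from probe sets paired with 1 gene. Of 101 genes with several tested probe sets, 0 had opposite calls and 8 had calls for only some of their probe sets.

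Intensities below 23.5, the 20th percentile of all values, were set to that floor, and log2 values were taken. A fold change of a gene near the floor is therefore understated, and one with a whole group at the floor is given as a lower bound. The 30 percent of probe sets with the lowest mean log2 value over the 4 arrays were left out, which removed 6824 and left 15922, of which 8769 are paired with 1 gene. Control probe sets were left out of the comparison. No further normalization was applied. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), which had 2 residual and 9.90 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. Every adjusted p-value of a gene comes from this model, and differences on the log2 scale are given with its standard error. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

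Before the data were examined, 18 gene lists with 303 genes were fixed by locus: flowering promoters, floral meristem and organ identity, flowering repressors, photoperiod and clock, shoot meristem, mitosis, replication, green leaf, vascular, trichome and guard cell, anther and pollen, gibberellin, cytokinin response, dark and sugar response, flavonoid pathway, wounding, heat shock, and senescence and defence. The annotation names 46 of these genes. A further 25 lists were defined by gene symbols after the annotation table had been seen and before any difference between the groups was computed. Each gene was represented by its brightest probe set. Lists with at least 3 tested genes were tested with camera in limma with a preset correlation of 0.01 between genes. P-values were adjusted over the 7 fixed or the 25 further lists. Camera was run again with an estimated correlation, a version that rests on the 2 residual degrees of freedom and so has little power here. The rotation test fry was run beside it.

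The genes named were, by a rule fixed before the data were examined, the 8 largest rises and 8 largest falls among called probe sets with 1 gene and groups that did not overlap, the 3 members with the smallest p-value of each of the 4 flowering lists, the 2 such members of each other fixed list, and 11 flowering genes in any case. Further list members given as examples, and genes named first in the closing section, were chosen after their values were seen.

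The procedure was tested on simulated data of 2 arrays against 2, with 200 of 15922 probe sets changed, in 20 simulations. It recovered 86.1 percent of 2-fold and 99.6 percent of 4-fold changes with 0 wrong signs. On average 14.35 of 200 calls were false, a share of 7.18 percent against the nominal 5. Gene lists were tested in the last simulation only, where 0 of 40 unchanged lists were called. Simulated genes varied independently of each other, so this does not cover lists of correlated genes. Their values were drawn from a normal distribution without a floor, so genes at or near the floor are not covered either. Far fewer probe sets changed there than the 2388 called in the data. The alternatives tried were the replicate block, leaving out each array, quantile normalization, median centring, floors at the 5th and 40th percentiles, a pseudocount in place of the floor, other filters on dim probe sets, no intensity trend, other thresholds, and for gene lists an estimated correlation, the mean of a gene's probe sets, and no probe sets marked as matching several genes.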

Results

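Transcript levels were measured with oligonucleotide arrays in shoot apices dissected from Arabidopsis thaliana of the Col-0 accession. The apex holds the shoot meristem with its youngest organ primordia. One group of plants grew for 30 days in short days, a day length under which this accession stays vegetative for long. The other group had 30 days of short days followed by 7 long days, which promote flowering. Each group had 2 samples on 1 array each. The labels do not say whether the samples of a group came from separate plantings, so the p-values measure only the spread between these samples, which may be technical. The authors' scaled intensities had medians of 214 and 220.5 on the short day arrays and of 207 and 211 on the shifted arrays. The 2 arrays of a group correlated at r = 0.985 in short days and r = 0.987 after the shift, across 15922 probe sets, which are not independent replicates. Arrays of different groups correlated at 0.942 to 0.948. The ratio of 3' to 5' signal of the actin control, a sign of RNA integrity, was 6.51 and 5.72 in short days and 8.27 and 4.64 after the shift. Other controls had lower ratios. GAPDH had 1.78 and 2.04 in short days and 2.65 and 1.57 after the shift, and ubiquitin 3.14 and 3.44 against 3.27 and 2.36.

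The comparison asks which transcripts differ between apices kept in short days and apices moved to long days. The largest rise among probe sets paired with 1 gene was that of AT5G44630, a terpene synthase gene, from an intensity of 16.9 ± 12.2 to 1194 ± 16.2 (mean ± SD, n = 2 per group). The largest fall was that of BCAT4, which encodes an aminotransferase of methionine chain elongation in the synthesis of aliphatic glucosinolates, from 5160.4 ± 362 to 98.3 ± 22.6. Flowering genes also differed, with rises of UFO, AGL42, SPT and FD and falls of AGL19 and SMZ. The 4 genes that the annotation names, of 15 in the flavonoid and anthocyanin list, all fell. Of the 15922 probe sets tested, limma called 1083 higher and 1305 lower after the shift at an adjusted p below 0.05, and at least 2-fold differences made up 310 of the rises and 602 of the falls.

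Among the rises, WSD1, a wax ester synthase gene, had a log2 difference of 4.45 ± 0.23 (SE, adjusted p = 1.4e-07) and AT4G19430 rose from 19.9 ± 13.4 to 452 ± 54.1 (adjusted p = 3.3e-07). For these and for AT5G44630 (5.61 ± 0.19, adjusted p = 4e-09), 1 of the 2 short day arrays lay at the floor set on low intensities, and AT4G00870, a gene of the bHLH transcription factor family, lay at the floor on both and was at least 9.94-fold higher after the shift. AT3G28500, which encodes an acidic ribosomal protein, rose from 510.45 ± 72.3 to 5161.5 ± 688, a log2 difference of 3.34 ± 0.13. BAT1, an acyltransferase gene of brassinosteroid metabolism, rose by 3.31 ± 0.28. AT1G02190 rose by 3.44 ± 0.24 and AT2G16210, also named REM24, by 2.92 ± 0.29, with 1 short day array at the floor. The size and the p-values of these rises depend on the floor, which hides the spread of values below it. With it at the 40th percentile AT5G44630 had 3.55, WSD1 2.496, AT4G19430 2.15, AT1G02190 2.15, BAT1 1.28, AT4G00870 1.20 and AT2G16210 0.93, all still called, and with a pseudocount in its place AT5G44630 had 4.95, WSD1 3.76, AT4G19430 3.49, BAT1 2.49 and AT2G16210 2.16. With the floor at the 5th percentile AT5G44630 had 6.37 (adjusted p = 3.9e-07), AT4G00870 4.96 (5.9e-05) and AT4G19430 4.69 (5.9e-06). Among the falls, BCAT4 had a log2 difference of -5.73 ± 0.15 (adjusted p = 1.3e-09), and AT2G25450, a dioxygenase gene of glucosinolate side chain modification, one of -4.44 ± 0.25. AT3G45160 fell from 2464 ± 424 to 107 ± 1.13, and AT5G59330 from 4069 ± 500.2 to 198 ± 26.0. The other 4 of the 8 largest falls were AT5G61660 at -4.19, AT1G56300 at -3.99, the peroxidase gene AT5G64110 at -3.81 and the carboxypeptidase-like gene scpl31 at -3.59. With the floor at the 40th percentile AT2G25450 had -2.81 (-3.70 with a pseudocount), AT5G61660 -3.46, AT1G56300 -3.04 and scpl31 -2.36, all still called.

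**Figure D1:**
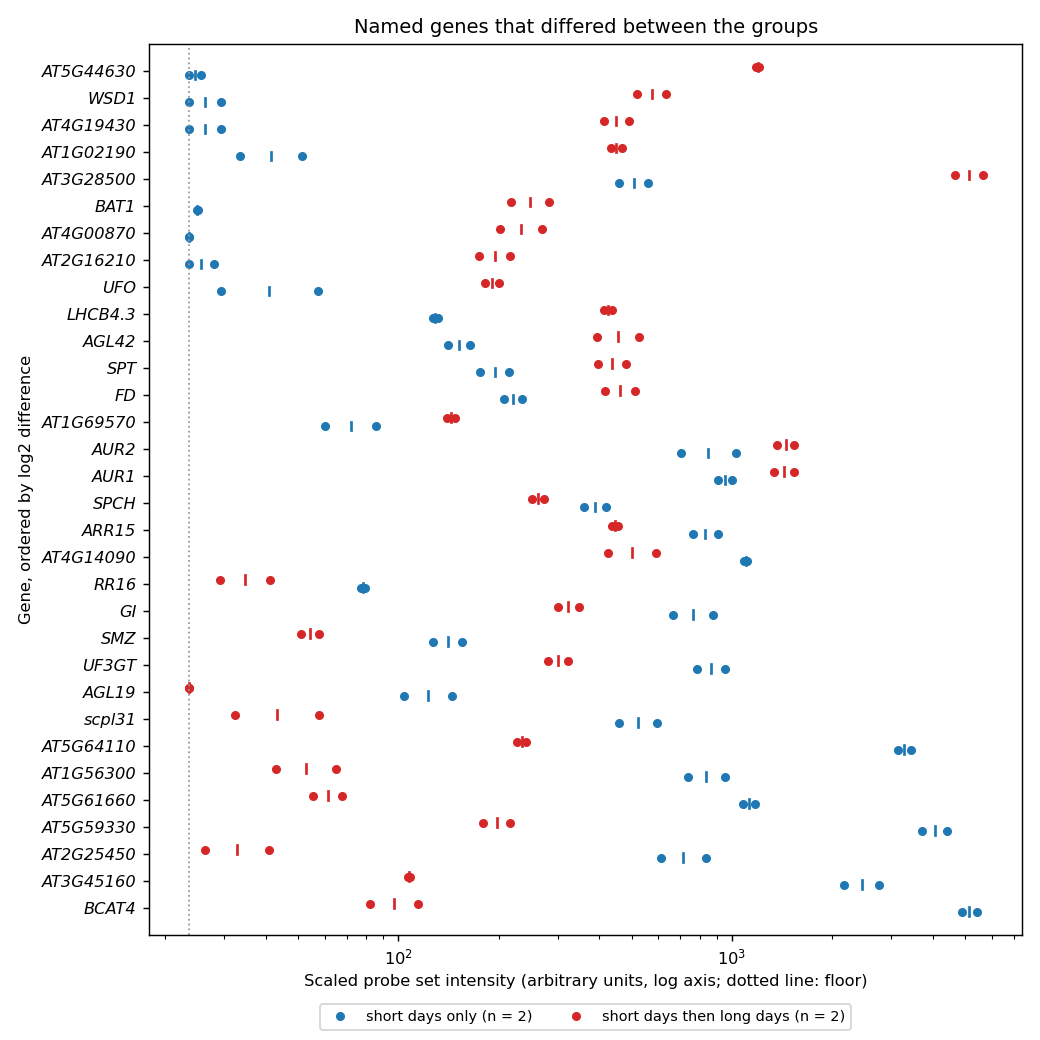
Scaled probe set intensity (arbitrary units, log axis) on each of the 4 arrays for the named genes that differed between the groups, ordered by log2 difference, with short day arrays in blue and shifted arrays in red. Points are single arrays, with values below the floor of 23.5 drawn at the floor (dotted line), and short bars are geometric means. BCAT4 lies lowest in the order, falling by 5.73 on the log2 scale, and AT5G44630 highest with a rise of 5.61.

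Of the 15 flowering promoters in the list, the annotation names 4, and 3 of these changed. AGL42, a MADS box gene, rose from 152 ± 16.3 to 460 ± 92.3 (log2 difference 1.59 ± 0.18, adjusted p = 7.7e-05). FD, which encodes the bZIP partner of the FT protein at the apex, rose from 221 ± 19.4 to 464 ± 68.9 (1.06 ± 0.16, adjusted p = 6.9e-04). AGL19, also a MADS box gene, fell from 124 ± 29.2 to the floor on both shifted arrays and was at least 5.22-fold lower. The list as a whole did not pass (camera adjusted p = 0.33, or 0.86 with an estimated correlation), though it did with the dimmest 50 percent of probe sets dropped (0.0045), when AGL19 was not tested. Of the floral meristem and organ identity genes, 3 of the 4 named by the annotation were bright enough to test. UFO, an F-box gene of floral meristem and petal development, rose from 43.4 ± 19.9 to 190 ± 13.1 (2.21 ± 0.32, adjusted p = 5.2e-04, or 0.90 and still called with the floor at the 40th percentile), and SPT, a bHLH gene of carpel development, from 195 ± 27.4 to 438 ± 61.0 (1.17 ± 0.17, adjusted p = 5.3e-04). PUCHI, an AP2 family gene of floral meristem identity, had a log2 difference of 0.88 ± 0.34 and did not pass (adjusted p = 0.11), though it did with quantile normalization (0.046). The list passed with an adjusted camera p of 0.0013, with an adjusted p of 0.52 with an estimated correlation, and adjusted over the list alone all 3 genes were higher.

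Of the flowering repressors, SMZ, an AP2-like gene, fell from 141 ± 19.9 to 54.3 ± 4.74 (-1.37 ± 0.26, adjusted p = 0.0037), and AGL18 at -0.54 ± 0.21 did not pass over all probe sets (adjusted p = 0.11). Adjusted over this list of 2 tested genes alone, both were lower. Such a pass says little, here or in the other short lists, as 4254 of the 15922 probe sets had an unadjusted limma p below 0.05. SNZ was too dim to test. The call of SMZ was lost without SD30 replicate 2 (adjusted p = 0.061), as were those of SMZ and AGL19 with the floor at the 40th percentile. SOC1, FUL, LFY, AP1, FLC, SVP, CO, FT and TFL1 were not analysed here. In the photoperiod and clock list, GI, a clock-controlled regulator of day length response, fell from 770.3 ± 149 to 324 ± 33.0 (-1.24 ± 0.15, adjusted p = 1.4e-04); the time of day at harvest is not given in the sources used here. AT1G69570, listed as CDF5, rose by 1.00 ± 0.26 (adjusted p = 0.022), a call lost without SD30 replicate 1 (adjusted p = 0.14), SD30_LD7 replicate 1 (0.10) or SD30_LD7 replicate 2 (0.14).

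All 4 measured members of the flavonoid and anthocyanin list fell, though only 2 passed without an intensity trend and 0 with no filter on dim probe sets. Some of these calls were also lost without SD30 replicate 1, SD30 replicate 2 or SD30_LD7 replicate 1. The other genes of this list of 15 are not named by the annotation and were not analysed here, so the pathway as a whole was not measured. UGT78D1, outside this list but close in name to its member UGT78D2, had 0.11 ± 0.11 and did not pass (adjusted p = 0.58). UF3GT, an anthocyanin glycosyltransferase gene, had the largest difference at -1.52 ± 0.14 (adjusted p = 1.2e-05), followed by AT4G14090 at -1.13 ± 0.15, DFR at -0.97 ± 0.17 and UGT78D2 at -0.60 ± 0.13. The list passed with an adjusted camera p of 7.4e-06, with an adjusted p of 0.27 with an estimated correlation. That estimate was -0.022, below the preset 0.01, so a higher correlation between these genes is not why the p-value rose. Of 11 type-A response regulators of cytokinin signalling in the list, the annotation names 2, and both fell. ARR15 had -0.90 ± 0.13 (adjusted p = 3.7e-04) and RR16, also named ARR16, had -1.17 ± 0.34 (adjusted p = 0.037). The RR16 call was lost without any 1 of the 4 arrays, with adjusted p from 0.059 without SD30_LD7 replicate 2 to 0.18 without SD30_LD7 replicate 1, and with quantile normalization (0.11), and with the floor at the 40th percentile RR16 was too dim to test. The Aurora kinase genes AUR1 and AUR2, the 2 that the annotation names of 17 genes in the fixed mitotic list, rose by 0.59 ± 0.11 and 0.77 ± 0.16 (adjusted p = 0.0038 and 0.0052). In the further list of mitosis and cytokinesis they were the 2 called among 20 genes, with AUR3 at -0.21 ± 0.15. That list did not pass (camera adjusted p = 0.12, or 0.77 with an estimated correlation), though it did with no filter on dim probe sets (0.0064, or 0.027 with a pseudocount as well). Without SD30 replicate 2 AUR1 and AUR2 missed the threshold (0.080 and 0.081), as did AUR1 without SD30_LD7 replicate 1 (0.057) and AUR2 without SD30_LD7 replicate 2 (0.077), and both without an intensity trend (0.057 and 0.088).

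Of the green leaf markers, 1 of 4 passed. LHCB4.3, an antenna protein gene, rose by 1.72 ± 0.16 (adjusted p = 1.7e-05), while RCA, the Rubisco activase gene, had -0.42 ± 0.15 (adjusted p = 0.085, or 0.041 without SD30 replicate 2) over all probe sets and was lower when adjusted over the list alone. The list had a mean log2 difference of 0.22 but a median of -0.22, and did not pass (adjusted p = 0.99). SPCH, a regulator of the stomatal lineage, was the 1 of 3 trichome and guard cell markers that fell, by 0.57 ± 0.15 (adjusted p = 0.026). That call was lost without any 1 array, with adjusted p from 0.078 without SD30 replicate 2 to 0.20 without SD30 replicate 1, with the floor at the 40th percentile (0.056) and without an intensity trend (0.065). TRY of the same list had 0.27 ± 0.20 (adjusted p = 0.44), and the list's mean of -0.05 and median of 0.14 differ in sign. No call was made for the 3 shoot meristem regulators (CLV3 -0.12 ± 0.28, ULT1 0.14 ± 0.11), the 3 gibberellin genes (GID1A -0.26 ± 0.12, GID1B 0.29 ± 0.17), the replication gene PRL (0.06 ± 0.11), EMS1 of the anther list (-0.32 ± 0.12) or WRKY53 of the senescence and defence list (-0.29 ± 0.33). EMS1 was lower when adjusted over its list alone, in which it was the 1 gene tested. The named members of the wounding and heat shock lists were too dim to test, and no member of the vascular or dark response lists was analysed here.

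Among the lists built from the annotation's gene symbols, 27 of the 69 plastid-encoded genes fell and the others did not pass, with a median log2 difference of -0.41. Examples were psbT of photosystem II at -0.99 ± 0.12, rps15 of the plastid ribosome at -0.86 ± 0.12 and ndhA of the NDH complex at -0.67 ± 0.11. The list passed with an adjusted camera p of 3.3e-17, with an adjusted p of 0.77 with an estimated correlation. Without SD30 replicate 1, 10 members were lower, without SD30 replicate 2, 14, without an intensity trend, 6, and with no filter on dim probe sets, 0. Of 26 nuclear photosynthesis genes, 4 fell and 2 rose, with a median of -0.21 and an adjusted camera p of 0.12, or 0.99 with an estimated correlation. The list passed without SD30 replicate 2 (0.0021), without SD30_LD7 replicate 1 (0.036) and with quantile normalization (0.028). Without SD30 replicate 1 this was 1 and 1 with a median of -0.09, without SD30 replicate 2 it was 2 and 1 (-0.28), without SD30_LD7 replicate 1 it was 3 and 1 (-0.30), and without SD30_LD7 replicate 2 it was 1 and 2 (-0.16), while with no filter 0 of the 26 passed. PORB, of chlorophyll synthesis, fell by 0.79 ± 0.11 (adjusted p = 3.5e-04). All 3 cold and LEA genes bright enough to test fell, COR15A with a log2 difference of -3.25 ± 0.27, COR15B of -2.06 ± 0.35 and COR47 of -1.68 ± 0.20. COR15B had -1.35 without SD30 replicate 1 and -2.77 without SD30 replicate 2, and with the floor at the 40th percentile it missed the threshold (adjusted p = 0.054) and COR15A had -1.82. With no filter all 3 missed it (0.11, 0.28 and 0.12). The list passed at an adjusted p of 3.6e-05, with an adjusted p of 0.77 with an estimated correlation. Of 11 beta glucosidase genes, 6 fell and 1 rose (list adjusted p = 0.028, or an adjusted p of 0.77 with an estimated correlation). BGLU33 had -2.52 ± 0.31 and BGLU44 -1.01 ± 0.11, while BGLU28 had 1.29 ± 0.39 and lost its call without any 1 array. Of this list 2 members were lower without SD30 replicate 1, SD30 replicate 2 or SD30_LD7 replicate 2, 3 without SD30_LD7 replicate 1, 1 with the floor at the 40th percentile, when BGLU33 had -0.50 and missed the threshold, and 0 with no filter. The beta glucosidase list missed the threshold without SD30 replicate 1 (adjusted p = 0.066), with the dimmest 50 percent dropped (0.069) and with no filter on dim probe sets (0.32, or 0.39 with a pseudocount as well), as did the cold list with no filter (0.13, or 0.11 with a pseudocount as well). The rotation test fry, which asks whether a list's genes moved on balance one way, gave adjusted p of 0.022 for the beta glucosidases, 0.056 for the plastid-encoded, 0.0998 for the cold, 0.076 for the flavonoid and 0.16 for the floral meristem genes. Of the further lists, fry also passed 2 that camera did not. These were serine carboxypeptidase-like genes (0.022, downward), and xyloglucan endotransglucosylases and GH9 cellulases (0.044, upward). Of the 16 carboxypeptidase-like genes tested, 5 fell and 2 rose, with a mean log2 difference of -0.40 but a median of -0.06.

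**Figure D2:**
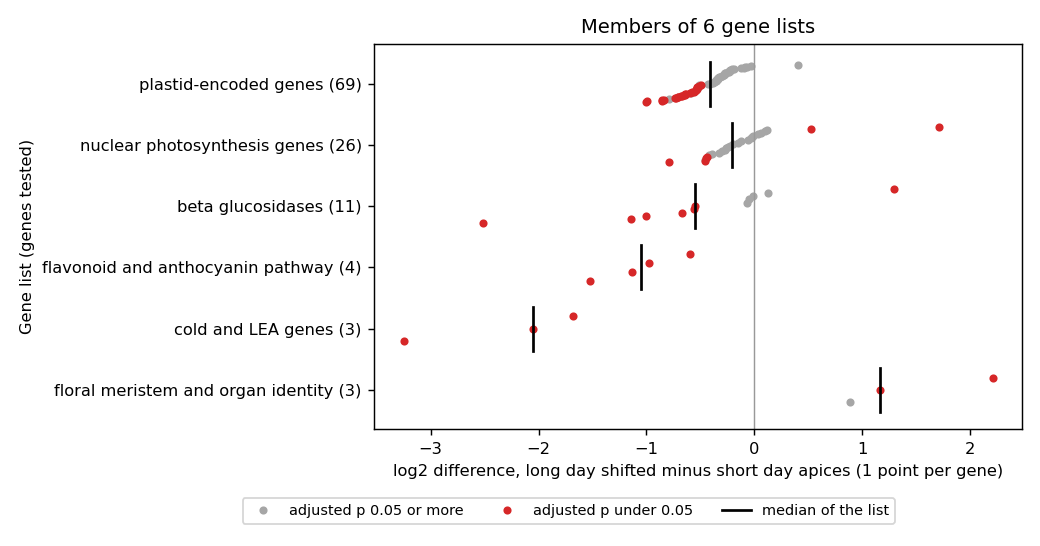
The log2 difference, shifted minus short day apices, of each tested member of 6 gene lists, 1 point per gene, with the number of genes tested beside each list. Red points passed at an adjusted p below 0.05, grey points did not, and black bars are list medians. The plastid-encoded genes centre on -0.41 with 27 of 69 in red, and the nuclear photosynthesis genes on -0.21.

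The shifted plants also had 7 more days of growth than the others, so day length and age are not separated in these samples. Leaving out 1 array gave 1058 to 1494 calls, and limma with no filter on dim probe sets gave 152, when 26 of the 32 named genes called missed the threshold. The log2 differences were unchanged without the filter. With no filter and a pseudocount, 1584 probe sets were called and 3 of the 32 missed the threshold. With arrays centred on their medians, 1329 probe sets were higher and 1066 lower, and with the dimmest 50 percent dropped 862 and 798, so the balance of rises and falls over all calls turned with the scaling and with the filter.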

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

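The search of the control probe sets, which entered no comparison, was made after the data were seen. The control probe set AFFX-r2-At-U12639_at had a mean intensity of 269 on the shifted arrays (230.4 and 307) against 17.95 on the short day arrays (25.2 and 10.7), a signal in data that the comparison did not use.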

How the results depend on the processing

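The alternatives without a filter but with a pseudocount, and median centring with a 2-fold minimum, were chosen after seeing the data. Relative to 2388 calls (1083 higher, 1305 lower), leaving out 1 array gave 1058 to 1494 calls, 475 to 615 higher and 583 to 879 lower, the lone array of a group being assumed to vary like the other group. No filter on dim probe sets gave 152 calls (44 higher, 108 lower). There 2557 probe sets at the floor had no spread, and the prior degrees of freedom fell from 9.90 to 0.716. No filter with a pseudocount gave 1584 (713 higher), with 1 probe set without spread and 5.61 prior degrees of freedom. Dropping the dimmest 50 percent left 862 higher and 798 lower. No intensity trend gave 1532 (596 higher). A 2-fold minimum gave 912 (310 higher, 602 lower), or 892 (352 higher, 540 lower) after median centring. The lowest correlation within a group moved from 0.985 to 0.988 with the floor at the 40th percentile, 0.987 with a pseudocount (0.987 also without the filter) and 0.989 with no filter. With camera and an estimated correlation 0 of 7 fixed and 0 of 25 further lists passed, against 2 and 3, with 1 of each at an unadjusted p below 0.05, and with the dimmest 50 percent dropped 1 further list passed, while the floral meristem and cold lists held too few genes to test. Fewer arrays, dropping the dimmest 50 percent and a 2-fold minimum lower counts by construction. Camera with an estimated correlation rests on the 2 residual degrees of freedom, which by itself raises its p-values. The estimate was below the preset 0.01 for the flavonoid (-0.022) and beta glucosidase (-0.071) lists. It was above 0.01 for the plastid-encoded (0.062), floral meristem (0.73) and cold (0.94) lists. With no filter the log2 differences stayed the same, so the lost calls came from the fitted spread and the adjustment over 22746 probe sets. For the remaining changes the cause was not tested.

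The replicate numbers do not pair the samples by their labels, and same-numbered arrays deviated from their group means with a correlation of 0.0466 over 2 pairs. A replicate block gave 2741 calls, which kept 2372 of the 2388 in the same direction. None of the 43 named genes reversed as a called value. Of the 32 called, 26 missed the threshold with no filter, 3 with no filter and a pseudocount, 3 with the floor at the 40th percentile, 3 with no intensity trend, 1 with quantile normalization, and 3 to 5 without 1 array, and 6 kept their call under every alternative run on them. With the dimmest 50 percent dropped, 15 were not tested. Median centring, the floor at the 5th percentile and a pseudocount changed no named gene's call. Signals near the floor limit the dimmer genes.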

Other observations

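The tests of the green tissue share, the REM genes and the glucosinolate genes below were chosen after their results had been seen in part; the others were fixed before. Within further lists that did not pass camera, single genes changed, named here after their values were seen; with no filter on dim probe sets, all genes named as called in this paragraph but PYK10 missed the threshold. Cell wall genes went both ways, and the list of xyloglucan endotransglucosylases and GH9 cellulases passed fry (adjusted p = 0.044). XTH16 and EXGT-A3, both xyloglucan endotransglucosylase genes, rose by log2 differences of 1.06 ± 0.11 and 0.88 ± 0.16, as did EXLA2 by 1.21 ± 0.16, while the cellulase gene GH9C2 had -0.73 ± 0.10 and EXPA15 had -0.51 ± 0.10 (SE, n = 2 per group). EXGT-A3 lost its call without SD30 replicate 2 or SD30_LD7 replicate 2, EXPA15 without any array but SD30_LD7 replicate 2, and both without an intensity trend. Of 17 organ patterning genes, 4 fell, among them NUB at -1.22 ± 0.15, SHI at -1.39 ± 0.18 and YAB5 at -1.20 ± 0.18, and 2 rose. Those 2 were UFO and SPT of the floral meristem list, whose 3 tested genes are all among the 17. Among 25 UDP-glycosyltransferase genes 4 rose, with UGT84A1 at 2.64 ± 0.32 and its neighbour UGT84A3 at 1.71 ± 0.31, and 3 fell, so that the list had a mean of 0.09 and a median of -0.19. For UGT84A1, 1 short day array lay below the floor, and with the floor at the 5th percentile 24 of these genes were tested and 3 rose. Without SD30 replicate 1, SD30 replicate 2 or SD30_LD7 replicate 1 only 1 fell, as without an intensity trend, and UGT84A3 lost its call without SD30_LD7 replicate 1. With the floor at the 40th percentile UGT84A1 had 0.57 and UGT84A3 0.28, and neither passed. THI2.1, a thionin gene, rose from 513 to 2008 and THI2.2 fell from 274 to 160, a mean of the 2 arrays in each case, but THI2.2 lost its call without any array but SD30_LD7 replicate 2. PYK10, a beta glucosidase gene of ER bodies outside the symbol pattern of that list, fell from 2388 ± 11.4 to 250.25 ± 37.1 (-3.26 ± 0.12, adjusted p = 1e-08).

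The adjusted camera p was 0.12 for mitosis and cytokinesis, 0.14 for xyloglucan endotransglucosylases and GH9 cellulases, 0.37 for carboxypeptidase-like genes and for the stomatal lineage, 0.42 for CYP71B genes, for histone H2B and replication, for auxin genes and for xylan, lignin and vascular genes, 0.70 for organ patterning, 0.72 for tubulins and 0.82 for tau glutathione transferases. It was 0.99 for AGAMOUS-like genes, anther and meiosis genes, UDP-glycosyltransferases, TRICHOME BIREFRINGENCE-LIKE genes, expansins, SWEET transporters, jasmonate and defensin genes, autophagy, ubiquitin-conjugating enzymes and splicing factors. The mean and the median had opposite signs for UDP-glycosyltransferases, expansins, autophagy and ubiquitin-conjugating enzymes, and the jasmonate list had a negative mean and median with an upward camera direction. Of the called probe sets, 1224 have no single gene named here (546 higher, 678 lower). The groups of 8681 of 15922 probe sets did not overlap (54.5 percent), where chance gives 33.3 percent.

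The lower plastid-encoded transcripts were weighed against 2 explanations. Their median log2 difference of -0.41 lay below all of 10000 random lists of nuclear genes matched on intensity (lowest -0.083), which argues against a bias that depends on brightness. The other was a smaller share of green tissue. The median log2 difference of the nuclear photosynthesis genes was higher by 0.20, and higher also without any 1 array (two-sided permutation p = 0.0028 over 26 and 69 genes, which are not independent). This argues against less green tissue as the whole cause only if it lowers both sets alike, which was not tested. The nuclear median difference of -0.21 had a bootstrap interval over genes of -0.31 to -0.03, which does not measure the spread between arrays. By array the nuclear median log2 value was 10.99 and 10.67 in short days against 10.77 and 10.68 after the shift, so the groups overlapped. A part played by less green tissue stays open. The plastid-encoded median log2 value exceeded the nuclear photosynthesis median by 1.05 and 1.09 on the short day arrays. After the shift the excess was 0.67 and 0.64. Plastid transcripts were thus lower relative to nuclear photosynthesis transcripts on both shifted arrays, and the cause stays open. Untested here are a difference in the priming of RNA without poly(A) tails, and the day length and age of the plants.

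Neighbouring genes tended to be called in the same direction. Of 2934 pairs of adjacent protein-coding genes tested, 47 were both higher or both lower, where 10000 shuffles of the calls gave 26.4 on average and 17 to 37 in the central part of the shuffles that leaves 5 percent outside (one-sided permutation p = 2e-04), while 26 pairs were called in opposite directions against 26.3. Without probe sets marked as matching several genes 46 pairs were left against 26.3 on average and 17 to 36 in the same central part. That step left 8414 of 8454 genes, so the marked probe sets were few and account for little of the excess. Examples are COR15B with COR15A, JAL33 with JAL34, BGLU45 with BGLU46, and UGT84A1 with UGT84A3, which are tandem relatives, and FD with AT4G35905. Cross-hybridisation between relatives through unmarked probe sets stays open, as does a hypothesis of shared local regulation.

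Further hypotheses arose from the largest changes. AT2G16210 is one of 5 genes that the annotation names REPRODUCTIVE MERISTEM (REM), B3 family genes, and of the other 3 tested, REM22 rose by 1.87 ± 0.35 and AT4G31615 by 0.50 ± 0.15 (REM22 without a call if SD30_LD7 replicate 2 is left out, or at 0.14 with the floor at the 40th percentile, AT4G31615 if any 1 array is left out, with that floor or without an intensity trend), while AT2G35310 had 0.35 ± 0.13 and did not pass. Those 3 may have shifted as a group (camera p = 0.0053, and p = 0.24 with an estimated correlation). BCAT4 and AT2G25450 act in glucosinolate synthesis, and of 4 other such genes tested, 3 fell, AT2G31790 with -1.70 ± 0.13, GTR2, a glucosinolate transporter gene, with -0.78 ± 0.13 and UGT74B1 with -0.49 ± 0.11 (no call without SD30 replicate 2, SD30_LD7 replicate 1 or an intensity trend), while AOP1 had -0.46 ± 0.20 and did not pass. Those 4 are consistent with a lower level of the pathway's transcripts (camera p = 2.3e-05, and p = 0.050 with an estimated correlation), with 36 genes in the list and most of them not analysed here. With no filter on dim probe sets, the 5 genes called in these 2 groups all missed the threshold.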
